A study of Mus musculus with 24 samples.

How the data were processed

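RNA sequencing libraries were made from iWAT and eWAT of C57BL6 mice given an AAV for irisin or GFP and fed HFD or chow for 18 weeks, per the labels. The 24 libraries form 8 groups of 3, and the assignment of each library to its depot, vector and diet follows the sample labels, which matched the column names of the deposited table. Per the labels' protocols the libraries were made from polyadenylated RNA. Per the submitters' processing notes the reads were aligned with HISAT2 2.0.5 and counted per gene with featureCounts 1.5.0-p3, and the deposited values are FPKM. The authors computed them from the length of the gene model. Whether the libraries keep the strand of the transcript is not given in the sources used here.

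The deposited table holds 54532 genes with identifier, symbol, position, length and biotype, 22046 of them protein coding. Symbols are those of the table, and rows were joined by gene identifier, since 103 symbols occur more than once. Another 8 numeric columns equal the means of the groups and were not used. The genome build is not given in the sources used here. Of the gene identifiers 54409 are in GENCODE release M21 (build GRCm38), 98.3% with the same position and 97.3% also with the same strand and name, and coordinates in the text are those of the deposited table.

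In each library every FPKM value times gene length was a whole multiple of 1 step within a tolerance of 0.01, for 100% of values, so that the reads per gene could be read back. They sum to 14.1 M to 19.7 M per library (median 16.4 M). The authors' scaling factor was 0.91 to 1.15 times that sum, with a geometric mean of 1.003, so the deposited scaling is not the plain sum of gene reads and the text uses it as it stands. A value of 1 FPKM in a gene of 2000 bases stands for 26.7 to 39.3 reads. No library was a copy of another.

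The choice of comparisons, tests, thresholds, 32 gene lists, naming rule and most alternatives was made before the data were examined. Within each depot 5 comparisons were made: irisin against GFP on HFD and on chow, HFD against chow in GFP and in irisin mice, and the vector by diet interaction. The difference of the irisin effect between depots was tested on HFD and on chow, for 12 comparisons in all. Genes with at least 0.5 FPKM in at least 3 of the libraries fitted were kept: 16125 in iWAT, 16274 in eWAT and 17687 over both depots. Linear models on log2(FPKM + 0.5) were fitted with limma 3.58.1 in R 4.3.3, with the 4 groups of a depot in 1 fit (8 groups for the depot difference) and moderated variances that follow the mean. P-values were adjusted by Benjamini and Hochberg over the genes tested, and genes with an adjusted p under 0.05 were called. With 3 against 3 libraries an exact permutation p is never under 0.1, which is why the moderated test was used. The planned count tests of edgeR and DESeq2 were not run, and limma's voom on the recovered reads took their place.

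Gene lists with at least 5 tested members were tested with camera at its preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Counts of called members are given over all genes and adjusted over the list alone. The lists described in the report were picked after the list results were seen. Genes were named by a fixed rule: Fndc5, Il33 and Il1rl1 in every comparison; the 8 largest rises and 8 largest falls among called protein-coding genes with a mean of at least 1 FPKM in a group and groups that do not overlap (5 and 5 without the overlap condition for interactions and depot differences); for each list described, up to 4 called members with the smallest adjusted p, or up to 2 members with the smallest p where none was called; and Ucp1, Adipoq, Lep, Foxp3, Adgre1 and Trem2 in every group. Genes outside the rule (Ckm, Adam7, Gm17720, Alb, Apoa1 and genes called only under an alternative) were chosen after their values were seen. Some genes that the rule names are not reported here. List scores are the mean log2(FPKM + 0.5) of a list's tested members in a library, less the median over the depot.

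Alternatives fixed beforehand were a pseudocount of 1 or 0.1, no filter or a filter of 1 FPKM, upper quartile and quantile scaling, a replicate block, a fit of only the groups compared, array weights, robust moderation, a fold minimum of 1 log2 unit and leaving out each library in turn. Further alternatives were chosen after seeing the data: limma's voom on the recovered reads, and all fits without the 4 libraries rich in other tissues (iWAT GFP HFD 1 and irisin chow 3, eWAT GFP chow 1 and GFP HFD 3). The model was tested on simulated data for 8 comparisons, drawn from each gene's mean and spread with Poisson reads and no correlation between genes, with 200 genes changed. In these 31% to 65% of 2-fold changes and 82% to 94% of 4-fold changes were recovered, and 2.68% to 8.14% of calls were false. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.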

Results

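White fat from 2 depots of C57BL6 mice was profiled by RNA sequencing of polyadenylated RNA: inguinal fat under the skin (iWAT) and epididymal fat in the abdomen (eWAT). The mice had received an adeno-associated virus (AAV) for irisin, a hormone cleaved from the product of Fndc5, or for the control protein GFP, and were fed a high-fat diet (HFD) or chow for 18 weeks. Each of the 8 combinations of depot, vector and diet had 3 libraries, 24 in all, and the series title names the IL-33 and ST2 pathway as the route under study. The recovered gene reads ranged from 14.1 M to 19.7 M per library, with a median of 16.4 M. Levels below are means ± SD in FPKM (n = 3 libraries per group), and effects are log2 fold changes ± SE on the log2(FPKM + 0.5) scale, which understates the change of genes with low values. A gene is called where limma's adjusted p was under 0.05. The labels do not say whether the 3 libraries of a group came from separate mice, so that p-values measure only the spread between these libraries. The depot labels matched the expression of Tbx15, a transcription factor of subcutaneous fat, and Wt1, a mesothelial transcription factor of visceral fat: on chow with GFP, Tbx15 was at 8.80 ± 2.42 FPKM in iWAT and 0.0411 ± 0.0407 in eWAT, and Wt1 at 8.78 ± 2.57 in eWAT and 0 in all 3 iWAT libraries.

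Several libraries carried transcripts of other tissues. All 3 iWAT libraries of irisin mice on chow held skeletal muscle transcripts, with list scores 2.41, 4.07 and 7.67 log2 units above the depot median and the muscle creatine kinase Ckm at 4.83, 17.2 and 279 FPKM. The iWAT library GFP HFD 1 scored 5.26 log2 units above the depot median for B cell markers, with the regulatory T cell factor Foxp3 at 2.27 FPKM, and the eWAT library GFP chow 1 scored 3.12. The eWAT library GFP HFD 3 held 291 FPKM of the epididymal gene Adam7, which was listed at 0 in the other 23 libraries. Macrophage transcripts were low in the iWAT library GFP chow 3 (Adgre1, the macrophage antigen F4/80, at 4.63 FPKM) and in the eWAT library irisin HFD 2 (Adgre1 32.3 and Trem2, a lipid receptor of macrophages, 10.4 FPKM). The latter was low only among eWAT HFD libraries, since eWAT chow libraries held at most 24.3 FPKM of Adgre1 and 4.69 of Trem2.

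**Figure D1:**
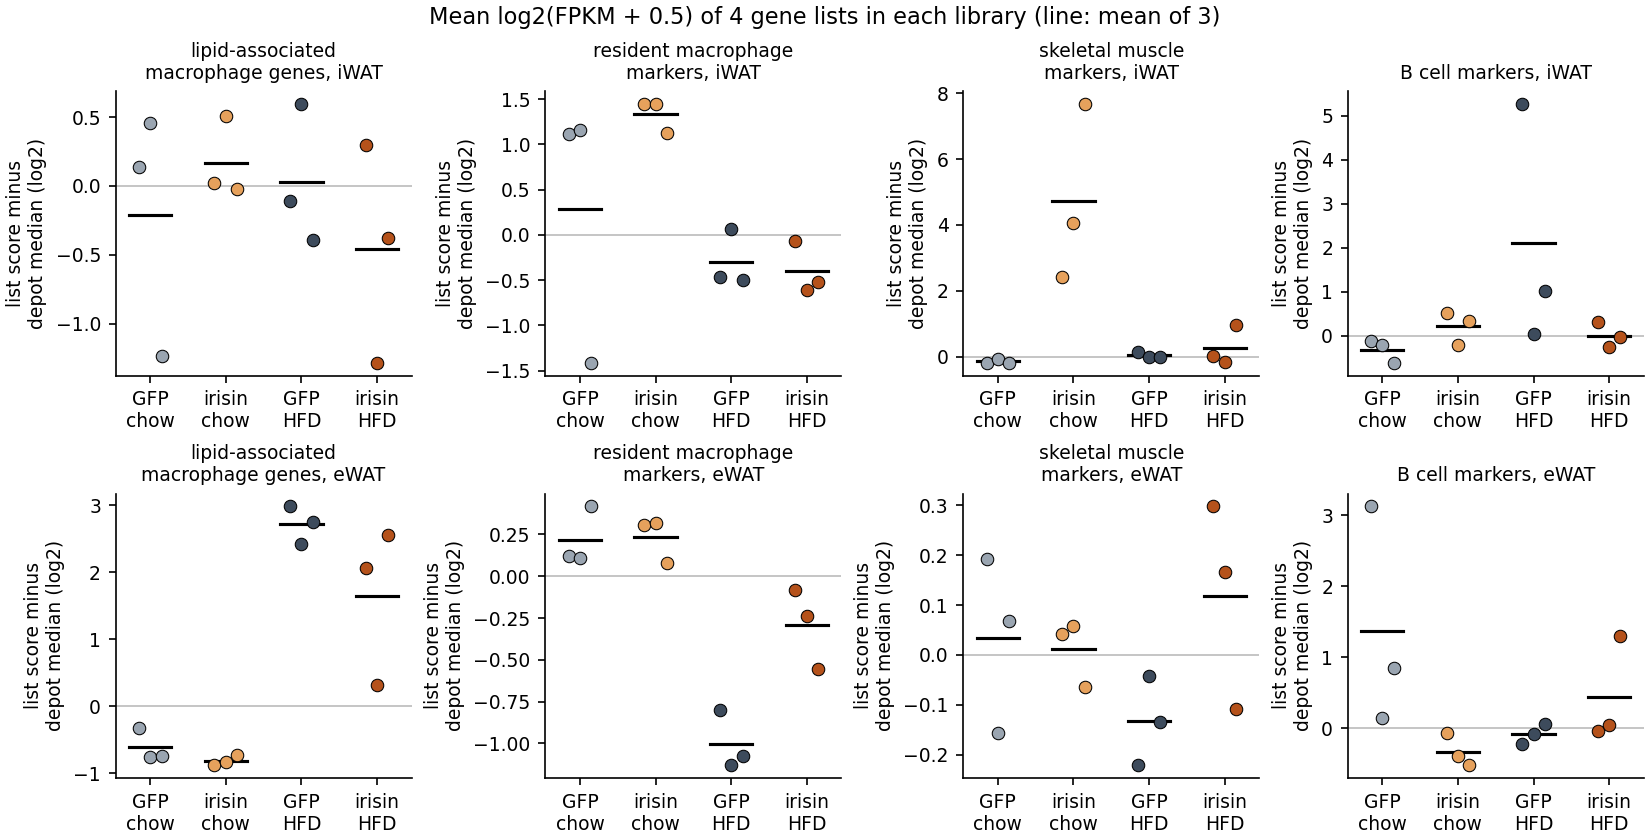
Each point is 1 library's mean log2(FPKM + 0.5) over a gene list, minus the median of its depot (y axis, log2 units), by vector and diet (x axis), with lines at the mean of 3 libraries. The muscle score is high in all 3 iWAT libraries of irisin mice on chow (up to 7.67), the B cell score in 1 iWAT library of GFP mice on HFD (5.26), and the lipid-associated macrophage score in eWAT on HFD in every library, lowest in irisin HFD 2 (0.32).

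Fndc5, the gene for the irisin precursor (ENSMUSG00000001334, chromosome 4, positions 129136999 to 129144593 on the plus strand, as the deposited table gives them), was read first as a check of the vector labels. In iWAT its level was 0.490 ± 0.299 FPKM in GFP mice on chow, 1.59 ± 1.20 in irisin mice on chow, 0.205 ± 0.0484 in GFP mice on HFD and 2.49 ± 1.86 in irisin mice on HFD. On HFD each irisin library of iWAT (0.392, 3.17 and 3.91) lay above each GFP library (0.258, 0.163 and 0.193), a log2 fold change of 1.79 ± 0.57 that was not called (adjusted p = 0.946). Groups of 3 and 3 lie apart in 10% of genes by chance. In eWAT Fndc5 was at 0.325 ± 0.171 and 0.886 ± 0.477 FPKM on chow and 2.60 ± 1.0 and 3.10 ± 1.96 on HFD in GFP and irisin mice, without a called vector effect (adjusted p = 0.953 on HFD and 0.939 on chow). The labels do not say which tissue the vector entered or which species' irisin sequence it carried, and a hormone made elsewhere need leave no transcript in fat.

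Il33, an alarm cytokine of stromal cells (ENSMUSG00000024810, chromosome 19, positions 29925114 to 29960718, plus strand), was at 3.42 ± 2.57, 5.87 ± 2.40, 2.89 ± 2.81 and 1.44 ± 0.218 FPKM in iWAT of GFP chow, irisin chow, GFP HFD and irisin HFD mice. In eWAT the same order of groups gave 9.99 ± 6.35, 7.93 ± 2.83, 5.96 ± 1.29 and 3.91 ± 1.63 FPKM. No vector effect on Il33 was called: the log2 fold change, irisin against GFP, was -0.50 ± 0.68 on HFD and 0.98 ± 0.68 on chow in iWAT, and -0.59 ± 0.41 and -0.22 ± 0.41 in eWAT (adjusted p = 0.954, 0.919, 0.614 and 0.997). Without the B-cell-rich iWAT library GFP HFD 1 the direction in iWAT on HFD turned to 0.14. Il1rl1, which encodes the IL-33 receptor ST2 (ENSMUSG00000026069, chromosome 1, positions 40429570 to 40465415, plus strand), was at 1.67 ± 0.670, 2.91 ± 0.367, 1.42 ± 0.163 and 1.17 ± 0.181 FPKM in iWAT and 2.15 ± 0.270, 1.60 ± 0.238, 3.66 ± 1.63 and 2.61 ± 1.18 in eWAT. Its vector effects were not called either, with log2 fold changes of -0.21 ± 0.23 and 0.70 ± 0.23 in iWAT on HFD and chow, where each irisin chow library lay above each GFP chow library (adjusted p = 0.946 and 0.919) and -0.41 ± 0.34 and -0.33 ± 0.34 in eWAT (adjusted p = 0.665 and 0.968). No other annotated gene of the deposited table overlapped Fndc5, Il33 or Il1rl1.

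**Figure D2:**
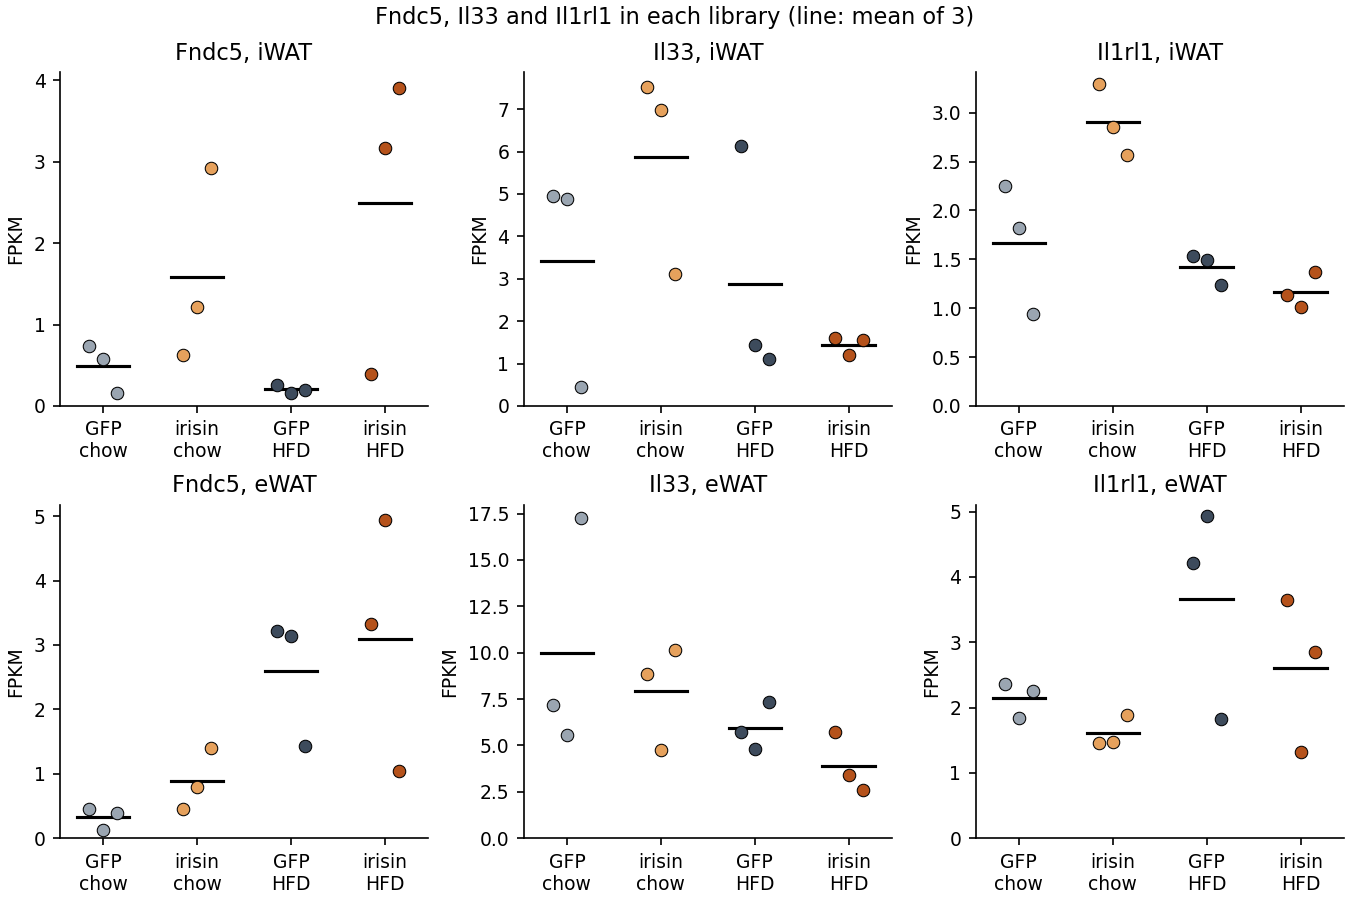
FPKM (y axis) of Fndc5, Il33 and Il1rl1 in each of the 24 libraries by vector and diet (x axis), iWAT above and eWAT below, with lines at the mean of 3 libraries. Fndc5 in iWAT on HFD lies between 0.392 and 3.91 in irisin mice and under 0.26 in GFP mice, while the Il33 values of irisin and GFP libraries overlap in each depot and diet.

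The marker genes fixed for every group are given as values. Ucp1, the uncoupling protein of thermogenic fat, was low throughout: in iWAT 0.0362 ± 0.0626 FPKM (GFP chow), 0.0129 ± 0.0223 (irisin chow), 0.400 ± 0.308 (GFP HFD) and 0.308 ± 0.115 (irisin HFD), and in eWAT 0 in all 3 libraries, 0.0110 ± 0.0191, 0.441 ± 0.301 and 0.131 ± 0.119 in the same order. The adipocyte hormone gene Adipoq was at 1690 ± 118, 1420 ± 93.2, 1440 ± 518 and 1720 ± 213 FPKM in iWAT and 2000 ± 326, 2030 ± 151, 649 ± 57.9 and 1150 ± 616 in eWAT. The leptin gene Lep was at 219 ± 110.0, 123 ± 12.6, 1170 ± 257 and 1430 ± 656 FPKM in iWAT and 258 ± 95.1, 148 ± 16.9, 820.0 ± 84.3 and 1140 ± 283 in eWAT. Foxp3 was at 0.103 ± 0.00641, 0.0931 ± 0.0535, 0.873 ± 1.21 and 0.0914 ± 0.0514 FPKM in iWAT and 0.227 ± 0.149, 0.120 ± 0.0651, 0.0911 ± 0.0674 and 0.118 ± 0.0624 in eWAT. Adgre1 was at 19.6 ± 13, 27.5 ± 4.32, 17.3 ± 10.9 and 14 ± 7.91 FPKM in iWAT and 20.7 ± 3.41, 15.7 ± 0.917, 157 ± 30.3 and 97.5 ± 58.4 in eWAT, and Trem2 at 3.20 ± 2.78, 3.62 ± 1.27, 3.26 ± 3.0 and 2.13 ± 1.83 in iWAT and 3.63 ± 1.04, 3.69 ± 0.756, 91.1 ± 24.7 and 50.8 ± 36.4 in eWAT.

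The comparison of irisin with GFP in iWAT on HFD asked what the vector changed in subcutaneous fat of mice on HFD. Mitochondrial and lipid-burning genes lay slightly higher in irisin mice and lymphocyte and interferon genes lower, but no single gene was called. All 50 tested nuclear genes of oxidative phosphorylation were higher in irisin libraries (median 0.38). Ndufs7 was at log2 0.44 and Cox6c at 0.50 (for the list, camera adjusted p = 4.95e-18, adjusted p = 0.326 with an estimated correlation). Higher, too, were 19 of 20 genes of fatty acid oxidation (median 0.46). Acads was at 0.51 and Cpt2 at 0.53 (for the list, camera adjusted p = 3.31e-08, adjusted p = 0.326 with an estimated correlation). Of the genes of adipocyte identity and lipid storage, 29 of 30 were higher (median 0.37). Mgll was at 0.48 and Fabp5 at 0.47 (for the list, camera adjusted p = 4.03e-06, adjusted p = 0.362 with an estimated correlation). Thermogenic and beige adipocyte genes were higher in 16 of 22 cases (median 0.15). Ebf2 was at 0.55 and Dio2, the deiodinase that activates thyroid hormone, at 0.94 (for the list, camera adjusted p = 0.0175, adjusted p = 0.362 with an estimated correlation). GFP HFD 1 scored lowest of the 6 libraries for each of these lists: -0.78 for oxidative phosphorylation and -0.49 for adipocyte genes, against -0.05 and 0.05 and 0.33 and 0.54 in the other GFP libraries.

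Among immune groups, interferon response genes were lower in 29 of 30 cases (median -0.39). Oas3 was at -0.91 and Mx1 at -1.31 (for the list, camera adjusted p = 3.06e-11, adjusted p = 0.326 with an estimated correlation). All 12 tested genes of MHC class II presentation were lower (median -1.0). H2-Oa, for example, was at -2.11 (for the list, camera adjusted p = 8.53e-08, adjusted p = 0.326 with an estimated correlation). So were all 10 B cell markers (median -2.22). Cd79b, a part of the B cell receptor, was at -2.88 (for the list, camera adjusted p = 2.26e-07, adjusted p = 0.326 with an estimated correlation). The 12 T and NK cell markers were all lower as well (median -1.53). Cd8b1 was at -2.02 (for the list, camera adjusted p = 4.00e-06, adjusted p = 0.326 with an estimated correlation). Regulatory T cell markers were lower in 9 of 10 cases (median -0.56). Batf was at -1.05 and Tigit at -0.92 (for the list, camera adjusted p = 9.45e-04, adjusted p = 0.326 with an estimated correlation). The IL-33, ST2 and type 2 list was lower in 11 of 15 genes (median -0.21). Il7r was at -2.14 and Myd88 at -0.40 (for the list, camera adjusted p = 0.0152, adjusted p = 0.326 with an estimated correlation). Apart from the interferon list, each of these immune lists scored highest in GFP HFD 1: 5.26 for B cells against 0.04 and 1.01 in the other GFP libraries, 1.13 for regulatory T cells against -0.17 and -0.24, and 0.53 for the IL-33 list against 0.06 and -0.03. Over all genes limma called 0 of 16125, with 431 at an unadjusted p under 0.05, and voom called 0, with 374. The lowest adjusted p was 0.880. Camera called 18 of 29 lists, of which 0 held with an estimated correlation and 0 with fry. With array weights 12 genes were called.

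On chow the same comparison in iWAT asked what the vector changed in subcutaneous fat without HFD. Skeletal muscle genes stood highest in irisin mice, with all 11 tested markers higher (median log2 5.36). Adjusted over the list alone 10 of them were called, and none over all genes (for the list, camera adjusted p = 1.16e-23, adjusted p = 0.125 with an estimated correlation). Myh4, a fast myosin heavy chain, was at 6.85 ± 1.06 (adjusted p = 0.356) and Pvalb, a calcium buffer of fast fibres, at 6.59 ± 1.15 (adjusted p = 0.356). All 10 nerve and Schwann cell markers were also higher (median 0.98), 7 of them called adjusted over the list alone. Ncmap was at 1.40 (for the list, camera adjusted p = 8.85e-13, adjusted p = 0.125 with an estimated correlation). The muscle rise is that of the transcripts described above. The muscle score was 2.41 or more in each irisin chow library and at most -0.07 in GFP mice on chow. Whether the nerve markers came with the muscle was not tested.

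Among stromal and immune groups, extracellular matrix genes were higher in 28 of 30 cases (median 0.54). Timp1 was at 1.38 and Col1a1 at 1.18 (for the list, camera adjusted p = 1.54e-07, adjusted p = 0.452 with an estimated correlation). All 14 resident macrophage markers were higher (median 0.99). Mgl2 was at 0.82 and Lyve1 at 1.54 (for the list, camera adjusted p = 2.20e-07, adjusted p = 0.452 with an estimated correlation). Their score was -1.42 in GFP chow 3, against 1.11 and 1.16 in the other GFP libraries. Endothelial markers were higher in 15 of 16 cases (median 0.28). Vwf, the von Willebrand factor gene, was at 1.17 as the only member called adjusted over the list alone (for the list, camera adjusted p = 0.00300, adjusted p = 0.453 with an estimated correlation). The IL-33, ST2 and type 2 list was higher in 11 of 15 genes (median 0.27). Il1rl1 was at 0.70 and Il4ra at 0.90 (for the list, camera adjusted p = 0.0113, adjusted p = 0.452 with an estimated correlation). Interferon response genes were higher in 25 of 30 cases (median 0.21). Dhx58 was at 0.51 and Oasl2 at 0.68 (for the list, camera adjusted p = 1.31e-04, adjusted p = 0.452 with an estimated correlation). All 50 nuclear genes of oxidative phosphorylation were lower (median -0.36). Cox5b was at -0.55 (for the list, camera adjusted p = 2.28e-17, adjusted p = 0.452 with an estimated correlation). Lower values were also found for 29 of 30 genes of adipocyte identity (median -0.33). Agpat2, a gene of triglyceride synthesis, was at -0.68 (for the list, camera adjusted p = 3.30e-05, adjusted p = 0.452 with an estimated correlation). Of the thermogenic genes 17 of 22 were lower (median -0.22). Otop1 was at -1.30 (for the list, camera adjusted p = 0.0313, adjusted p = 0.452 with an estimated correlation). Over all genes limma called 0 of 16125 (688 at an unadjusted p under 0.05, voom 0, with 654). Camera called 20 of 29 lists, of which 0 held with an estimated correlation and 2, muscle and nerve, with fry. Leaving out irisin chow 1 called 7 muscle genes, leaving out irisin chow 3 called Atp2a1 and Myh4, and array weights called 2248 genes.

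HFD against chow in iWAT of GFP mice gave the diet effect of the control vector. Mest, an imprinted gene, rose by 5.26 ± 0.91 (219.5 ± 93.7 against 8.82 ± 11.6 FPKM). Sfrp5, a secreted Wnt antagonist of adipocytes, rose by 3.91 ± 0.56 (182 ± 53.8 against 13.8 ± 11.1 FPKM) and the oxytocin receptor gene Oxtr by 4.87 ± 0.75. Lipf, a lipase gene known from the stomach, rose by 4.65 ± 0.62, Tph2, a tryptophan hydroxylase, by 4.47 ± 0.97 and the ubiquitin-like gene Ubd by 4.20 ± 0.77. The choline transporter gene Slc5a7 rose by 4.01 ± 0.82 and Crtac1 by 3.11 ± 0.38. Cyp2f2, a cytochrome P450 gene, fell by 5.23 ± 0.63 (2.58 ± 2.33 against 100.1 ± 31.4 FPKM). Cfd, which encodes adipsin, fell by 3.64 ± 0.68 (1889 ± 1894 against 17230 ± 3189 FPKM) and Cyp2e1 by 3.32 ± 0.73. Prtn3, a serine protease gene, fell by 3.44 ± 0.40, Ppl by 2.84 ± 0.41 and the amino acid transporter gene Slc43a1 by 2.80 ± 0.42. Tst fell by 2.73 ± 0.39 and the beta-3 adrenergic receptor gene Adrb3 by 2.58 ± 0.53 (adjusted p of these 16 genes from 0.0118 to 0.0426). Il33 at -0.15 ± 0.68, Il1rl1 at -0.13 ± 0.23 and Fndc5 at -0.44 ± 0.57 were not called (adjusted p = 0.929, 0.799 and 0.715).

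All 23 cell cycle genes were higher on HFD (median 1.11), 17 of them called adjusted over the list alone. Cdk1 rose by 1.5 ± 0.25 as the only member called over all genes (for the list, camera adjusted p = 6.34e-11, adjusted p = 0.783 with an estimated correlation). Of 19 cholesterol biosynthesis genes, 4 rose over all genes and 6 adjusted over the list alone (median 0.60). Hmgcs1 rose by 1.65, Sc5d by 1.14 and Stard4 by 1.07 (for the list, camera adjusted p = 1.09e-05, adjusted p = 0.783 with an estimated correlation). Among 22 genes of de novo lipogenesis, 9 were lower and 1 higher adjusted over the list alone (median -0.47). Fads1 fell by 1.35 and Acaca, acetyl-CoA carboxylase, by 1.66 over all genes (for the list, camera adjusted p = 0.00733, adjusted p = 0.783 with an estimated correlation). All 50 nuclear genes of oxidative phosphorylation were lower on HFD without a called member (median -0.41). Ndufa1 was at -0.83 and Cox6c at -0.86 (for the list, camera adjusted p = 2.30e-10, adjusted p = 0.783 with an estimated correlation). Of the subcutaneous depot markers 4 of 6 were lower adjusted over the list alone (median -0.87). Tbx15 fell by 1.09 and Sfrp2 by 1.85 (for the list, camera adjusted p = 2.35e-04, adjusted p = 0.443 with an estimated correlation). Among 17 clock genes (median -0.39), Dbp fell by 1.18 and Cry1 rose by 0.87 (for the list, camera adjusted p = 0.0110, adjusted p = 0.783 with an estimated correlation). B cell markers were higher in 10 of 10 cases, 2 of them called adjusted over the list alone (median 2.40). Ighm rose by 1.68 (for the list, camera adjusted p = 1.02e-04, adjusted p = 0.783 with an estimated correlation). MHC class II genes were higher in 12 of 12 with none called (median 0.83). H2-DMb1 was at 1.42 and H2-Ob at 2.37 (for the list, camera adjusted p = 0.00276, adjusted p = 0.783 with an estimated correlation). Beside these lists stand the scores of GFP HFD 1, 5.26 for B cells and -0.78 for oxidative phosphorylation. Over all genes limma called 382, 233 higher and 149 lower, and voom 368. The majority turned without GFP chow 3 (199 higher and 295 lower) and without GFP HFD 3 (188 and 215). Camera called 11 of 29 lists, none of which held with an estimated correlation, and fry called 1, the depot markers. The count fell to 0 without GFP chow 1 or without GFP HFD 2 and to 202 without GFP chow 2, and a fit of only these 6 libraries called 0. Without the 4 libraries rich in other tissues 251 genes were called, 76.1% of them higher against 61.0%.

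The same diet comparison in irisin mice had the muscle-bearing libraries as its chow group. Lipf rose by 4.51 ± 0.62, Mest by 4.50 ± 0.91 (149.5 ± 104 against 4.78 ± 2.71 FPKM), Oxtr by 4.30 ± 0.75, Crtac1 by 3.97 ± 0.38, Ubd by 3.76 ± 0.77 and Tph2 by 3.69 ± 0.97. Rnase2a, a ribonuclease gene of the eosinophil family, rose by 4.04 ± 0.60 and the integrin gene Itgad by 3.87 ± 0.89. Cyp2f2 fell by 5.22 ± 0.63 (3.37 ± 3.85 against 106 ± 19.9 FPKM) and Cxcl13, a chemokine that draws B cells, fell by 5.27 ± 1.36 (0.738 ± 0.875 against 41.2 ± 9.61 FPKM). The other 6 of the 8 falls were in muscle genes: Myh4 fell by 6.27 ± 1.06, Atp2a1 by 6.0 ± 1.03, Tnnt3 by 5.94 ± 1.10, Ckm fell by 5.30 ± 1.08, Tnni2 by 5.05 ± 1.08 and Actn3 fell by 5.03 ± 0.99. Ckm was at 4.83 to 279 FPKM in the chow libraries (adjusted p of these 16 genes from 0.00145 to 0.0403). Il1rl1 fell by 1.03 ± 0.23 (adjusted p = 0.0221, 1.17 ± 0.180 against 2.91 ± 0.367 FPKM). Il33 at -1.63 ± 0.68 and Fndc5 at 0.38 ± 0.57 were not called (adjusted p = 0.152 and 0.699).

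Of 30 adipocyte genes, 12 rose and 2 fell, or 14 and 2 adjusted over the list alone (median 0.79). Lep rose by 3.45 ± 0.38, Fabp5 by 2.07, Sfrp5 by 3.57 and Npr3 by 3.06 (for the list, camera adjusted p = 1.03e-06, adjusted p = 0.460 with an estimated correlation). Of 20 fatty acid oxidation genes 5 rose, 12 adjusted over the list alone (median 0.75). Acadm rose by 1.22 and Slc25a20 by 1.11 (for the list, camera adjusted p = 9.50e-07, adjusted p = 0.460 with an estimated correlation). Of 19 cholesterol genes 5 rose, 8 adjusted over the list alone (median 0.64). Hmgcs1 rose by 2.51 and Sc5d by 1.69 (for the list, camera adjusted p = 9.50e-07, adjusted p = 0.426 with an estimated correlation). Of 22 thermogenic genes 5 rose and 2 fell, or 7 and 2 adjusted over the list alone (median 0.42). Otop1 rose by 2.86 and Ebf2 fell by 1.16 (for the list, camera adjusted p = 0.0229, adjusted p = 0.463 with an estimated correlation). Interferon response genes fell in 11 of 30 cases, 16 adjusted over the list alone (median -0.72). Irf7 fell by 0.94, Oas2 by 2.10 and Oas3 by 1.54 (for the list, camera adjusted p = 4.03e-08, adjusted p = 0.426 with an estimated correlation).

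Resident macrophage markers fell in 3 of 14 cases, 11 adjusted over the list alone (median -1.83). Clec10a, a lectin gene, fell by 2.57 (for the list, camera adjusted p = 5.13e-06, adjusted p = 0.460 with an estimated correlation). Of 8 eosinophil and mast cell markers 5 were lower adjusted over the list alone (median -1.84). The mast cell genes Cpa3 and Mcpt4 fell by 2.70 and 3.10 (for the list, camera adjusted p = 0.0287, adjusted p = 0.591 with an estimated correlation). Stromal progenitor genes fell in 4 and rose in 1 of 19 cases, 7 and 1 adjusted over the list alone (median -1.14). Pdgfra fell by 1.60 and Ly6a by 1.97 (for the list, camera adjusted p = 7.62e-04, adjusted p = 0.426 with an estimated correlation). Muscle markers fell in 8 of 11 cases, 10 adjusted over the list alone (median -4.90, for the list, camera adjusted p = 8.43e-08, adjusted p = 0.426 with an estimated correlation). Nerve markers fell in 6 of 10 cases, 8 adjusted over the list alone (median -1.67, for the list, camera adjusted p = 3.76e-06, adjusted p = 0.426 with an estimated correlation). In all, limma called 1453 genes, 778 higher and 675 lower, and voom 1337. Under upper quartile scaling the majority turned, with 671 higher and 733 lower. It also turned with the fold minimum (397 and 455), in a fit of only the groups compared (1041 and 1115) and without irisin HFD 1 (565 and 646). Camera called 17 of 29 lists, of which 0 held with an estimated correlation and 8 with fry. Leaving out 1 library gave 588, 464 and 391 genes without irisin chow 1, 2 and 3, 819 without irisin HFD 2 and 266 without irisin HFD 3.

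The vector by diet interaction in iWAT tested whether the diet effect differed between irisin and GFP mice. All 50 nuclear genes of oxidative phosphorylation had a more positive diet effect with irisin (median 0.73). Cox5b differed by 0.96 and Cox7c by 1.08 (for the list, camera adjusted p = 4.73e-26, adjusted p = 0.307 with an estimated correlation). Interferon response genes had a more negative diet effect with irisin in 29 of 30 cases (median -0.62). Dhx58 differed by -1.0 and Oas3 by -1.5 (for the list, camera adjusted p = 1.24e-10, adjusted p = 0.307 with an estimated correlation). Of the lists described here muscle markers differed most, 8 of 11 called adjusted over the list alone (median -5.06). Pvalb differed by -6.89 and Mylpf by -5.76 (for the list, camera adjusted p = 9.83e-12, adjusted p = 0.307 with an estimated correlation). The IL-33, ST2 and type 2 list had a more negative diet effect in 12 of 15 genes (median -0.58). Myd88 differed by -0.72 (for the list, camera adjusted p = 0.00147, adjusted p = 0.307 with an estimated correlation). Fndc5, Il33 and Il1rl1 differed by 0.82 ± 0.81, -1.48 ± 0.97 and -0.90 ± 0.32 (adjusted p = 0.784, 0.696 and 0.688). The diet calls of the vectors overlapped, with 192 genes that rose in both, against 11.2 for independent lists, and 93 that fell in both, against 6.24. Of the genes that rose in GFP mice 232 of 233 had the same sign in irisin mice, and 148 of the 149 that fell. For the interaction limma called 0 of 16125 genes (996 at an unadjusted p under 0.05, voom 0, with 885), so that the larger count of diet calls in irisin mice is not shown to be a difference. Camera called 21 of 29 lists, of which 0 held with an estimated correlation or fry. GFP HFD 1 and the muscle-bearing irisin chow libraries, described above, enter this comparison too.

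In eWAT on HFD, irisin was compared with GFP in the visceral depot. Genes of lipid-associated and inflammatory macrophages lay lower in irisin mice and resident macrophage markers higher, again with no single gene called. The lipid-associated list was lower in 25 of 28 genes (median log2 -1.20, for the list, camera adjusted p = 1.16e-09, adjusted p = 0.557 with an estimated correlation). Spp1, the osteopontin gene, was at -2.81 ± 0.83 and the scavenger receptor gene Msr1 at -1.30 ± 0.39 (adjusted p = 0.533 and 0.533). The list's scores on HFD were 2.06, 0.32 and 2.55 in irisin libraries and 2.98, 2.42 and 2.75 in GFP libraries. Resident macrophage markers were higher in 10 of 14 cases (median 1.08, for the list, camera adjusted p = 3.19e-06, adjusted p = 0.376 with an estimated correlation), 9 of them called adjusted over the list alone and none over all genes. Lyve1 was at 1.85 ± 0.35 and the lectin gene Mgl2 at 1.44 ± 0.27 (adjusted p = 0.393 and 0.393).

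All 50 nuclear genes of oxidative phosphorylation were higher with irisin (median 0.23). Ndufb3 was at 0.67 and Ndufb10 at 0.41 (for the list, camera adjusted p = 1.68e-09, adjusted p = 0.578 with an estimated correlation). Adipocyte genes were higher in 27 of 30 cases (median 0.50). Retn, the resistin gene, was at 1.43 and Cfd at 1.57 (for the list, camera adjusted p = 2.98e-07, adjusted p = 0.557 with an estimated correlation). Fatty acid oxidation genes were higher in 19 of 20 (median 0.40, for the list, camera adjusted p = 1.97e-06, adjusted p = 0.557 with an estimated correlation). Lipogenic genes were higher in 19 of 22 (median 0.39). Pnpla3 was at 0.90 and Thrsp at 1.44 (for the list, camera adjusted p = 1.95e-04, adjusted p = 0.557 with an estimated correlation). All 16 endothelial markers were higher (median 0.43). Cldn5, a tight junction gene, was at 0.89 and Kdr at 0.66 (for the list, camera adjusted p = 5.32e-05, adjusted p = 0.557 with an estimated correlation). Erythrocyte markers were higher in 5 of 5 (median 1.08). Hba-a2, a globin gene, was at 1.15 (for the list, camera adjusted p = 0.00864, adjusted p = 0.557 with an estimated correlation). All 24 cell cycle genes were lower (median -0.52). Mki67 was at -0.95 and Pcna at -0.74 (for the list, camera adjusted p = 5.89e-07, adjusted p = 0.557 with an estimated correlation). Interferon response genes were lower in 25 of 30 (median -0.24). Rsad2, an antiviral enzyme, was at -0.66 (for the list, camera adjusted p = 1.95e-04, adjusted p = 0.557 with an estimated correlation). Eosinophil and mast cell markers were lower in 7 of 9 (median -0.86). Cma1, a chymase gene, was at -1.56 (for the list, camera adjusted p = 0.00673, adjusted p = 0.557 with an estimated correlation). Irisin HFD 2 stood apart in several of these lists: it scored 0.68 for adipocyte genes against -0.20 and -0.34 in the other irisin libraries, 0.14 for oxidative phosphorylation against -0.21 and -0.50, 0.13 for lipogenic genes against -0.34 and -0.42, and 0.01 for the cell cycle against 0.85 and 1.49. Over all genes limma called 0 of 16274 (1510 at an unadjusted p under 0.05, voom 0, with 1564). Camera called 11 of 30 lists, of which 0 held with an estimated correlation or fry. Without GFP HFD 2 the genes Cd5l, Gclm, Ptgr1, Prdx1 and Gsr were called, without irisin HFD 3 Ccl24, Retnla and Gm17545, and array weights called 2213 genes.

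On chow, irisin against GFP in eWAT addressed the visceral depot without HFD. All 30 interferon response genes were higher in irisin mice (median log2 0.41, for the list, camera adjusted p = 4.82e-14, adjusted p = 0.379 with an estimated correlation), 8 of them called adjusted over the list alone and none over all genes. Cxcl10, a chemokine gene, was at 0.82 ± 0.19 and Rsad2 at 0.97 ± 0.23 (adjusted p = 0.674 and 0.696). All 16 endothelial markers were higher as well (median 0.75). Tek was at 0.43 and Esam at 0.77 (for the list, camera adjusted p = 2.49e-12, adjusted p = 0.379 with an estimated correlation). Clock genes were higher in 12 of 17 cases (median 0.29). Per1 was at 0.57 and Dbp at 1.39 (for the list, camera adjusted p = 0.0119, adjusted p = 0.379 with an estimated correlation). All 13 B cell markers were lower, 9 of them called adjusted over the list alone (median -1.83). Cd79b was at -2.41 and Pax5 at -1.39 (for the list, camera adjusted p = 8.57e-13, adjusted p = 0.379 with an estimated correlation). MHC class II genes were lower in 12 of 12 (median -0.32). H2-Ob was at -1.36 (for the list, camera adjusted p = 0.00104, adjusted p = 0.688 with an estimated correlation). The B cell score was 3.12 in GFP chow 1, against 0.14 and 0.85 in the other GFP libraries. Extracellular matrix genes were lower in 23 of 30 (median -0.13). Fn1 was at -0.60 and Thbs1 at -0.84 (for the list, camera adjusted p = 0.00492, adjusted p = 0.688 with an estimated correlation). Of 16274 genes limma called 0 (845 at an unadjusted p under 0.05, voom 0, with 853). Camera called 11 of 30 lists, of which 0 held with an estimated correlation or fry. Leaving out the 4 libraries rich in other tissues brought the camera calls to 7, leaving out GFP chow 2 called Igkj2 and leaving out GFP chow 3 called Gm17720.

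HFD against chow in eWAT of GFP mice gave the diet effect of the control vector in visceral fat, and macrophage genes led the rises. Mmp12, the macrophage elastase, rose by 8.29 ± 0.77 (338 ± 183 against 0.551 ± 0.541 FPKM). Gpnmb, a glycoprotein of lipid-laden macrophages, rose by 7.26 ± 0.72 (589.6 ± 178 against 3.39 ± 1.35 FPKM). Spp1 rose by 7.09 ± 0.83 and Atp6v0d2, a subunit of the vacuolar proton pump, by 7.09 ± 0.58. Ubd rose by 6.68 ± 0.31 (211 ± 17.8 against 1.64 ± 0.769 FPKM), Vsig8 by 6.43 ± 0.60, the ubiquitin ligase gene Rnf128 by 6.24 ± 0.67 and Tm4sf19 by 5.97 ± 0.62. Cfd fell by 5.93 ± 0.56 (202 ± 53.1 against 12350 ± 3112 FPKM), Cyp2e1 by 5.84 ± 0.81 (23.9 ± 3.45 against 1420 ± 346 FPKM) and Cyp2f2 by 4.56 ± 0.66. Retnla, a secreted marker of alternatively activated macrophages, fell by 4.11 ± 0.61 (49.7 ± 6.15 against 896 ± 282 FPKM) and Adrb3 by 3.91 ± 0.58. Orm3, an acute phase protein gene, fell by 3.70 ± 0.61, the angiotensinogen gene Agt by 3.61 ± 0.55 and Mogat1, a monoacylglycerol acyltransferase gene, by 3.53 ± 0.44. The adjusted p of these 16 genes ranged from 4.32e-06 to 0.00236. Fndc5 rose by 1.87 ± 0.45 (adjusted p = 0.0116), and Il33 at -0.56 ± 0.41 and Il1rl1 at 0.57 ± 0.34 were not called (adjusted p = 0.351 and 0.246).

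Of 28 lipid-associated macrophage genes, 23 rose and none fell, with 24 called adjusted over the list alone (median log2 3.32). Lgals3, a galectin gene, rose by 4.05 ± 0.45 (for the list, camera adjusted p = 1.95e-13, adjusted p = 0.660 with an estimated correlation). Resident macrophage markers fell in 9 of 14 cases and rose in 2, or 10 and 2 adjusted over the list alone (median -1.80). Lyve1 fell by 3.21, Timd4 by 2.52 and Cd209g by 2.11 (for the list, camera adjusted p = 6.18e-04, adjusted p = 0.660 with an estimated correlation). Cell cycle genes rose in 23 of 24 cases, 24 adjusted over the list alone (median 1.59). Ube2c rose by 1.82 and Mki67 by 2.17 (for the list, camera adjusted p = 9.51e-12, adjusted p = 0.660 with an estimated correlation). Extracellular matrix genes rose in 16 and fell in 1 of 30 cases, 17 and 1 adjusted over the list alone (median 0.67). Col6a3 rose by 1.36 and Postn by 1.96 (for the list, camera adjusted p = 1.69e-04, adjusted p = 0.660 with an estimated correlation). Nuclear genes of oxidative phosphorylation fell in 30 of 50 cases, 36 adjusted over the list alone (median -0.50). Ndufb10 fell by 0.88 (for the list, camera adjusted p = 3.66e-12, adjusted p = 0.660 with an estimated correlation).

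Lipogenic genes fell in 10 and rose in 2 of 22 cases, 13 and 3 adjusted over the list alone (median -0.75). Acaca fell by 2.32 and Thrsp by 3.06, while Insig1, an inhibitor of sterol synthesis, rose by 1.86 (for the list, camera adjusted p = 0.00141, adjusted p = 0.660 with an estimated correlation). Cholesterol genes rose in 7 and fell in 1 of 19 cases, 9 and 1 adjusted over the list alone (median 0.58). Msmo1 rose by 1.08 (for the list, camera adjusted p = 0.0141, adjusted p = 0.660 with an estimated correlation). Adipocyte genes rose in 6 and fell in 14 of 30 cases, 6 and 15 adjusted over the list alone (median -0.60). Retn fell by 3.44 and Fabp5 rose by 2.06 (for the list, camera adjusted p = 0.0188, adjusted p = 0.672 with an estimated correlation). Mesothelial markers fell in 7 of 11 cases, 11 adjusted over the list alone (median -1.69). Wt1 fell by 1.69 (for the list, camera adjusted p = 1.69e-04, adjusted p = 0.660 with an estimated correlation). B cell markers fell in 5 of 13 cases, 9 adjusted over the list alone (median -1.81, for the list, camera adjusted p = 0.00551, adjusted p = 0.660 with an estimated correlation), beside the B cell score of 3.12 in GFP chow 1. Over all genes limma called 4310, 2396 higher and 1914 lower, and voom 4384. The majority turned with upper quartile scaling (2117 higher and 2341 lower) and quantile scaling (2198 and 2359). Camera called 10 of 30 lists, of which 0 held with an estimated correlation and 7 with fry, which called 9 in all. The count was 2643 without GFP HFD 1 and 2670 without the 4 libraries rich in other tissues.

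**Figure D3:**
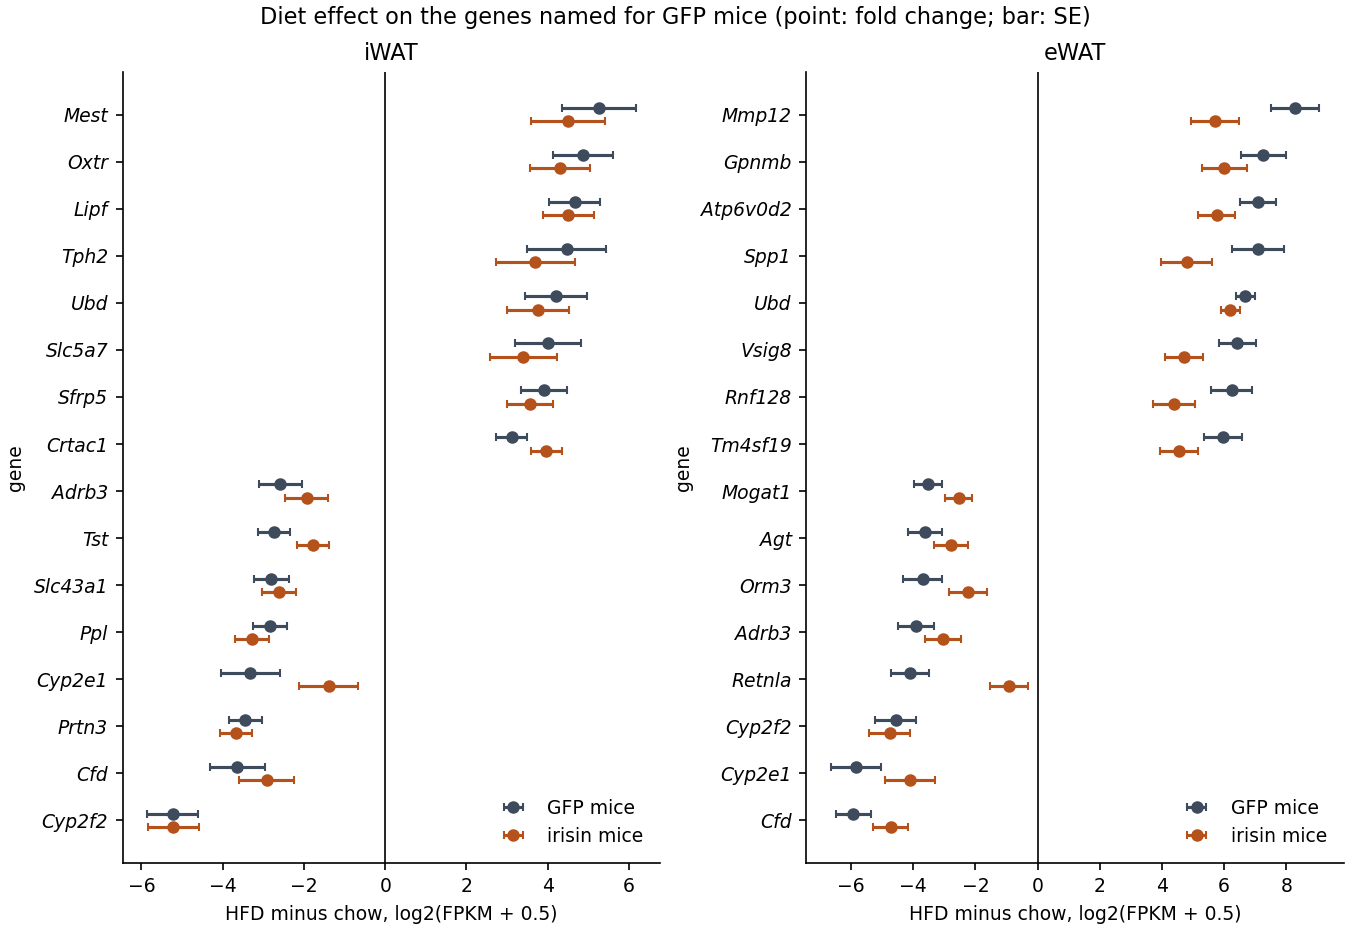
Diet effect (x axis, HFD minus chow, log2(FPKM + 0.5)) of the 16 genes with the largest rises and falls in GFP mice of each depot (y axis), for GFP and irisin mice. Points are fold changes and bars their SE. Both vectors lie on the same side of 0 for each gene shown, with the widest gap for Retnla in eWAT (-4.11 in GFP and -0.92 in irisin mice).

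In eWAT of irisin mice the diet effect had the same leading genes in part. Ubd rose by 6.2 ± 0.31 (213 ± 76.6 against 2.29 ± 0.533 FPKM) and Gpnmb by 5.99 ± 0.72 (281 ± 265 against 2.46 ± 0.935 FPKM). Atp6v0d2 rose by 5.76 ± 0.58, Mmp12 by 5.70 ± 0.77, Spp1 by 4.80 ± 0.83, Vsig8 by 4.71 ± 0.60, Slc5a7 by 4.92 ± 0.34 and Tph2 by 4.85 ± 0.57. Cyp2f2 fell by 4.76 ± 0.66, Cfd by 4.72 ± 0.56 (834 ± 852 against 15450 ± 1037 FPKM) and Cyp2e1 by 4.10 ± 0.81. Serpina3b fell by 3.04 ± 0.34. Adrb3 fell by 3.03 ± 0.58, the gelatinase gene Mmp9 by 3.0 ± 0.42 and Prtn3 by 2.83 ± 0.33 (adjusted p of these genes from 9.59e-06 to 0.00906). Fndc5 at 1.25 ± 0.45, Il33 at -0.93 ± 0.41 and Il1rl1 at 0.49 ± 0.34 were not called (adjusted p = 0.0761, 0.138 and 0.346).

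Lipid-associated macrophage genes rose in 22 of 28 cases, 22 adjusted over the list alone (median log2 2.24), with irisin HFD 2 the lowest HFD library for this list. Lgals3 rose by 3.23 ± 0.45 (for the list, camera adjusted p = 9.73e-13, adjusted p = 0.543 with an estimated correlation). Cell cycle genes rose in 15 of 24 cases, 23 adjusted over the list alone (median 1.37). Ube2c rose by 1.91 and Top2a by 1.65 (for the list, camera adjusted p = 6.32e-11, adjusted p = 0.543 with an estimated correlation). Extracellular matrix genes rose in 16 of 30 cases, 21 adjusted over the list alone (median 0.95). Col6a2 rose by 1.31 and Col12a1 by 1.64 (for the list, camera adjusted p = 5.17e-10, adjusted p = 0.497 with an estimated correlation). MHC class II genes rose in 7 of 12 cases, 9 adjusted over the list alone (median 1.38). Ctss, a cathepsin gene, rose by 2.95 and H2-Ab1 by 1.42 (for the list, camera adjusted p = 6.14e-05, adjusted p = 0.543 with an estimated correlation). Cholesterol genes rose in 6 of 19 cases, with 11 higher and 1 lower adjusted over the list alone (median 0.59). Lss rose by 0.96 (for the list, camera adjusted p = 6.45e-04, adjusted p = 0.543 with an estimated correlation).

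Interferon response genes fell in 5 of 30 cases, 5 adjusted over the list alone (median -0.40). Cxcl10 fell by 1.19 and Irf7 by 0.89 (for the list, camera adjusted p = 4.66e-04, adjusted p = 0.543 with an estimated correlation). Nuclear genes of oxidative phosphorylation fell in 8 of 50 cases, 14 adjusted over the list alone (median -0.40). Ndufs7 fell by 0.70 (for the list, camera adjusted p = 5.72e-09, adjusted p = 0.543 with an estimated correlation). Mesothelial markers fell in 3 of 11 cases, 5 adjusted over the list alone (median -1.47). Wt1 fell by 1.53 (for the list, camera adjusted p = 7.90e-04, adjusted p = 0.543 with an estimated correlation). In all, limma called 2831 genes, 1541 higher and 1290 lower, and voom 2988. With upper quartile scaling 1350 were higher and 1640 lower, and with quantile scaling 1373 and 1598. Camera called 12 of 30 lists, of which 0 held with an estimated correlation and 7 with fry, which called 9 in all. Leaving out 1 library gave 1574, 1225 and 1116 genes without irisin chow 1, 2 and 3, 1283 without irisin HFD 1 and 1923 without irisin HFD 3, but 4165 without irisin HFD 2. A fit of only these 6 libraries called 1393.

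The vector by diet interaction in eWAT tested whether the visceral response to HFD differed between the vectors. Lipid-associated macrophage genes had a smaller diet effect with irisin in 25 of 28 cases (median log2 difference -1.07, for the list, camera adjusted p = 6.36e-05, adjusted p = 0.639 with an estimated correlation). Its HFD part, irisin against GFP on HFD, had a mean of -1.07, and of -0.41 without irisin HFD 2. The members with the smallest p went the other way, the chemokine receptor gene Ccr2 at 1.02 and Saa3 at 2.22. All 30 interferon response genes had a more negative diet effect with irisin (median -0.76, for the list, camera adjusted p = 6.61e-17, adjusted p = 0.314 with an estimated correlation), 4 of them called adjusted over the list alone. Rsad2 differed by -1.62 ± 0.32 (adjusted p = 0.703) and Cxcl10 by -1.13. All 13 B cell markers had a more positive diet effect with irisin, 7 of them called adjusted over the list alone (median 2.41, for the list, camera adjusted p = 2.62e-11, adjusted p = 0.614 with an estimated correlation). Ighd differed by 3.01 and Cd79a by 3.43, beside the B cell score of 3.12 in GFP chow 1. Fndc5, Il33 and Il1rl1 differed by -0.62 ± 0.63, -0.38 ± 0.58 and -0.08 ± 0.48 (adjusted p = 0.909, 0.925 and 0.978). The diet calls of the vectors overlapped in 1232 genes that rose, against 227 for independent lists, and 906 that fell, against 152, with 3 called in opposite directions. Of 16274 genes limma called 1 (658 at an unadjusted p under 0.05, voom 0, with 578). It was Gm17720, a predicted gene named after its values were seen, at a log2 difference of 5.74 (adjusted p = 0.0169). The call rests on 0 to 5 reads per library and was kept without GFP chow 1, 2 or 3 (with 2 genes called without GFP chow 2) but not without any of the other 9 libraries. Camera called 10 of 30 lists, of which 0 held with an estimated correlation or fry.

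The difference of the irisin effect between the depots was tested over all 24 libraries. On chow, all 11 skeletal muscle markers had a higher irisin effect in iWAT than in eWAT, 10 of them called adjusted over the list alone (median log2 difference 5.37, for the list, camera adjusted p = 2.92e-29, adjusted p = 0.0151 with an estimated correlation). Myh4 differed by 6.86 ± 1.14 and Tnnt3, a troponin gene of fast muscle, by 6.07 ± 1.20 (adjusted p = 0.152 and 0.171). Nerve and Schwann cell markers did so in 10 of 10 cases, 6 adjusted over the list alone (median 1.02, for the list, camera adjusted p = 3.21e-12, adjusted p = 0.0151 with an estimated correlation). Dhh differed by 0.81. In eWAT on chow Ckm was at 0 FPKM with either vector, and Myh4 at 0.00799 with GFP and 0.00332 with irisin. For such genes the difference between depots is close to the iWAT effect alone. Fndc5, Il33 and Il1rl1 differed between the depots by 0.26 ± 0.76, 1.20 ± 0.85 and 1.03 ± 0.42 on chow and by 1.70 ± 0.76, 0.09 ± 0.85 and 0.21 ± 0.42 on HFD, none of them called. Of 17687 genes limma called 0 on HFD (443 at an unadjusted p under 0.05, voom 0, with 378) and 0 on chow (557, voom 0, with 524). Camera called 11 of 31 lists on HFD, of which 0 held with an estimated correlation or fry, and 19 on chow, of which muscle and nerve held with both. Without the 4 libraries rich in other tissues Ckm, Mylpf, Atp2a1 and Myh4 were called on chow, and 10 genes without iWAT irisin chow 1, 9 without irisin chow 3 and 1 without iWAT GFP chow 2. The fit without the 4 libraries still held irisin chow 1 and 2 of iWAT, which carry muscle transcripts too. On HFD 3 genes were called without eWAT GFP HFD 2 and 1 without iWAT GFP HFD 1.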

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

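The tests of muscle pieces, of the source of Fndc5 and of the macrophage genes in this part were chosen only after the results were seen.

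Gm17720, a predicted gene (ENSMUSG00000091041, chromosome 8, positions 110082803 to 110102753 on the minus strand), drew attention because its diet effect in eWAT differed between the vectors in the interaction test, by a log2 difference of 5.74 (adjusted p = 0.0169). Its reads were 1, 1 and 5 in GFP chow, 0, 0 and 0 in GFP HFD, 0, 0 and 0 in irisin chow and 1, 1 and 1 in irisin HFD libraries, so that the fitted value is no measure of a fold change, and the gene overlaps Zfp612 on the opposite strand.

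Skeletal muscle markers (median log2 difference 5.37) and nerve and Schwann cell markers (1.02) drew attention because the irisin effect on chow differed between iWAT and eWAT in a test of the difference itself (adjusted p = 0.0151 for each with an estimated correlation). In iWAT alone the same camera test gave an adjusted p of 0.125 for each list. Muscle genes such as Ckm and Myh4 were near 0 in eWAT on chow, so that this depot could hardly show an irisin effect on them. The fit of both depots also pooled the small spread of such eWAT values into the error of the difference. Pieces of skeletal muscle in the libraries could account for the muscle part. Of the 11 tested members, 10 were higher in every iWAT irisin chow library than in every GFP chow library. That count is no separate support, since the list was flagged from these same libraries. A gene such as Ckm, at most 1.15 FPKM in the other iWAT groups, also passed the filter only through them. An effect of the irisin vector on fat is not excluded, since the muscle score spread over 5.25 log2 units within the 3 irisin chow libraries but lay above the GFP libraries in each. Dissection and vector cannot be told apart here, because the same 3 libraries carry both. The nerve markers were not tested separately.

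Fndc5 was higher in each irisin than each GFP library of iWAT on HFD (log2 1.79 ± 0.57, adjusted p = 0.946), a difference that limma did not call. Muscle in these libraries was set against it: at the highest ratio of Fndc5 to Ckm in the muscle-bearing irisin chow libraries (0.129), muscle on top of the highest GFP HFD value (0.258) would give at most 0.405 FPKM in an irisin HFD library, and all 3 lay above the bound of their own Ckm, which argues against muscle as the whole source. Transcripts of the injected vector in fat might be another, but the log2 fold change of Fndc5 in eWAT on HFD was 0.10 ± 0.45, which a vector that reached only iWAT would also give. The 2 depots therefore leave this open, and a biological rise of the mouse gene was not tested apart from the vector.

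In eWAT on HFD lipid-associated macrophage genes lay lower in irisin than in GFP libraries and resident macrophage markers higher, which limma called for no member over all genes. The library irisin HFD 2, with fewer macrophage transcripts than the other eWAT HFD libraries, may carry much of the lower part. Without it the mean log2 fold change of the lipid-associated list was -0.41, against -1.07 with it. It was picked as the lowest HFD library on this list, so that leaving it out had to shrink the difference. A lower share of macrophages of every kind would not by itself raise the resident list, whose score averaged 0.71 log2 units higher in irisin libraries. Each irisin library lay above each GFP library on that list, with 3.65 at the lowest against 3.40 at the highest before the depot median was subtracted. This rise belongs to the pattern as it was picked from the same libraries, so it is no separate test of that explanation. An effect of the irisin vector stays open, since the lipid-associated scores differed by -1.07 on average but overlapped. Before the depot median was subtracted, the highest irisin library was at 5.91 and the lowest GFP library at 5.78. With 3 libraries per group, such an effect cannot be told from other differences between libraries.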

How the results depend on the processing

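The fits with voom on recovered reads and without the 4 libraries rich in other tissues were chosen only after seeing the data, and the tests on other splits of the libraries were written beforehand. Among gene and list results outside the counts of calls, 6376 values under an alternative kept their direction and their side of the threshold, 609 lost it, 42 gained it, 2 moved by more than their spread and 33 changed direction. Of the counts of calls 309 stayed within 1.5 times and 99 did not. Robust moderation, the filter of 1 FPKM and both scalings moved no count of called genes beyond 1.5 times, and the scalings moved the share of higher calls by at most 9.3 points. That turned the majority from higher to lower calls for HFD in eWAT of both vectors, and with upper quartile scaling in iWAT of irisin mice. The planned count tests of edgeR and DESeq2 were not run. A gene above the filter can still rest on few reads, as Gm17720 shows, whose mean in eWAT irisin HFD libraries was 2.31 FPKM.

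Replicate numbers were not used to pair the libraries, since not every same-number correlation was over 0.1: 9 of 18 were in iWAT, 3 of 18 in eWAT and 2 of 12 across depots, against 10 of 36, 5 of 36 and 6 of 24 for different numbers. The median correlation in iWAT was 0.0966 for the same and -0.0531 for different numbers. With the replicate block the interaction in eWAT called 0 genes against 1, and no other count of called genes moved beyond 1.5 times.

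Counts of camera calls fell with an estimated correlation to 0 in each comparison except the depot difference on chow, where 2 of 19 held. In iWAT the estimate ran from 0.0294 for immediate early genes to 0.901 for B cell markers, with 0.870 for oxidative phosphorylation, against the preset of 0.01. Members of the iWAT lists thus moved together more than the preset assumes, which makes its p-values too small. With fry, which asks only whether a list's genes move on balance one way, the irisin effect in iWAT kept 0 of 18 lists on HFD and 2 of 20 on chow, the HFD effect in iWAT 1 of 11 in GFP and 8 of 17 in irisin mice, the irisin effect in eWAT 0 of 11 on HFD and on chow, the HFD effect in eWAT 7 of 10 in GFP and 7 of 12 in irisin mice (fry called 9 in each), both interactions 0 (of 21 in iWAT and 10 in eWAT), and the depot difference 0 of 11 on HFD and 2 of 19 on chow.

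Counts of called genes moved as follows, and apart from fewer genes, libraries or a stricter fold the cause was not tested. Without a filter the irisin effect called 3 genes in iWAT on HFD, 1 on chow, 2 in eWAT on HFD and 3 on chow, the HFD effect in iWAT 161 in GFP and 894 in irisin mice, the interactions 2 in iWAT and 6 in eWAT, and the depot differences 1 on HFD and 5 on chow. With array weights the same order of irisin effects gave 12, 2248, 2213 and 1, the HFD effect in iWAT 3898 and 7509, that in eWAT of irisin mice 9817, the interaction in eWAT 19 and the depot differences 2 and 8. The fit of only the groups compared called 0 genes for HFD in iWAT of GFP mice against 382, 1393 in eWAT of irisin mice against 2831, and 4 for irisin in eWAT on chow against 0. The fold minimum left 852 of 1453 in iWAT of irisin mice, 1976 of 4310 in eWAT of GFP mice and 1197 of 2831 in eWAT of irisin mice. A pseudocount of 0.1 called 1 gene for irisin in eWAT on HFD and 1 on chow, and a pseudocount of 1 or voom called 0 for the interaction in eWAT against 1. Without the 4 libraries rich in other tissues HFD called 251 genes in iWAT of GFP mice against 382 and 2670 in eWAT of GFP mice against 4310. The same fits called 1 gene for irisin in eWAT on HFD (Igkv5-48) and 1 on chow (Mir6904), 0 for the interaction in eWAT and 4 for the depot difference on chow. Camera calls moved to 7 for irisin in eWAT on chow against 11 and to 16 for HFD in eWAT of GFP mice against 10.

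Leaving out each library in turn gave, as lowest and highest counts of called genes: irisin in iWAT 0 and 0 on HFD, 0 and 7 on chow; HFD in iWAT 0 and 494 in GFP, 266 and 1211 in irisin mice; interaction in iWAT 0 and 0; irisin in eWAT 0 and 5 on HFD, 0 and 1 on chow; HFD in eWAT 2643 and 4025 in GFP, 1116 and 4165 in irisin mice; interaction in eWAT 0 and 2; depot difference 0 and 3 on HFD, 0 and 10 on chow. The camera calls ranged, in the same order, from 12 to 18, 9 to 20, 9 to 13, 13 to 18, 18 to 23, 8 to 14, 6 to 14, 9 to 16, 11 to 13, 8 to 14, 8 to 15 and 16 to 22.

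Among named genes, directions changed only where the gene was not called. For the irisin effect in iWAT on HFD, Il33 moved from -0.50 to 0.05 with array weights and 0.14 without the libraries rich in other tissues. For irisin in eWAT on HFD, Il33 came to 0.00 with array weights and Fndc5 to -0.21 without the libraries rich in other tissues. Array weights gave 0.28 for Il33 and 0.23 for Il1rl1 in the interaction in eWAT. For Fndc5 in the depot difference on chow they gave -0.16, and leaving out the libraries rich in other tissues gave -0.30. Leaving out each library in turn turned further directions. In iWAT, Il33 ranged from -0.88 to 0.14 (without GFP HFD 1) for irisin on HFD. For HFD in GFP mice it ranged from -0.98 to 0.27, with 0.27, 0.27, 0.11 and 0.24 without GFP chow 1, chow 2, HFD 2 and HFD 3. Il1rl1 there ranged from -0.40 to 0.07 (without GFP chow 1). Fndc5 ranged from -0.05 (without irisin HFD 3) to 1.10 for HFD in irisin mice. In eWAT, Fndc5 ranged from -0.29 to 0.62 for irisin on HFD, with -0.21, -0.04 and -0.29 without GFP HFD 3, irisin HFD 1 and irisin HFD 2. For irisin on chow, Il33 ranged from -0.53 to 0.25, with 0.25 and 0.09 without GFP chow 3 and irisin chow 2. For the interaction in eWAT, Il1rl1 ranged from -0.45 to 0.26, with 0.01, 0.06, 0.16, 0.01 and 0.26 without GFP chow 2, GFP HFD 1, GFP HFD 2, irisin chow 3 and irisin HFD 2. For the depot difference on HFD, Il1rl1 ranged from -0.14 to 0.58, with -0.03 and -0.14 without GFP HFD 2 and irisin HFD 2 of eWAT. Il33 there ranged from -0.29 to 0.73, with -0.06 and -0.13 without GFP HFD 3 and irisin HFD 3 of eWAT and -0.16 and -0.29 without GFP HFD 2 and 3 of iWAT. Fndc5 ranged from -0.18 to 0.63 in the depot difference on chow, with -0.01 and -0.18 without GFP chow 3 and irisin chow 3 of iWAT. The cause was not tested.

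The 6 libraries of each comparison of 2 groups make 10 splits, which cannot give a share under 0.05. The real split and the highest other called 0 and 7 genes for irisin in iWAT on HFD and 0 and 2 on chow (10 of 10 splits as large each), 382 and 14 for HFD in iWAT of GFP mice and 1453 and 1 in irisin mice (1 of 10 each), 0 and 1 for irisin in eWAT on HFD and 0 and 2 on chow (10 of 10 each), and 4310 and 0 for HFD in eWAT of GFP mice and 2831 and 1 in irisin mice (1 of 10 each). Of 100 splits drawn, 100 called as many as the real 0 for the interaction in iWAT (highest other 890), 16 as many as the real 1 in eWAT (highest other 2), and 100 as many as the real 0 for the depot difference on HFD (highest other 353) and on chow (highest other 4). A real count of 0 is reached by every split, so those counts say nothing about chance, while for the interaction in eWAT chance is not excluded. Splits with 890 and 353 calls against a real 0 point to a structure of the samples, whose source was not tested.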

Other observations

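All observations in this part were chosen after seeing the data. The diet effect was shared between the depots beyond the overlap of independent lists. In GFP mice 110 genes rose on HFD in both depots (32.0 for independent lists) and 82 fell in both (16.8), against 7 and 2 that went opposite ways, and in irisin mice 263 rose (71.6) and 165 fell (49.7), against 5 and 12. Genes that rose in both depots of GFP mice include Tph2 (4.47 in iWAT and 4.85 in eWAT, log2), Slc5a7 (4.01 and 4.81), Oxtr (4.87 and 3.05), the transferrin receptor gene Tfr2 (2.42 and 2.55), Mfge8, a bridge for the uptake of dying cells (1.63 and 2.80), and Lep (2.51 and 1.73). Genes that fell in both include the paraoxonase gene Pon1 (-2.33 and -2.52), the glutamate transporter gene Slc1a3 (-2.06 and -2.39), the thrombomodulin gene Thbd (-1.77 and -2.62) and the glutathione peroxidase gene Gpx3 (-2.53 and -1.68).

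The brain-type creatine kinase gene Ckb went opposite ways: in GFP mice it fell in iWAT (-0.80) and rose in eWAT (2.18), and in irisin mice it fell (-0.88) and rose (1.40) likewise. In GFP mice the growth factor gene Fgf1 (2.17 and -1.19), the secretogranin gene Scg3 (1.47 and -1.34) and the potassium channel gene Kcnj15 (1.12 and -1.11) rose in iWAT and fell in eWAT. In irisin mice Spp1 fell in iWAT (-2.77) and rose in eWAT (4.80).

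In eWAT Retnla was at 896 ± 282 FPKM in GFP chow, 895 ± 216 in irisin chow, 49.7 ± 6.15 in GFP HFD and 669 ± 623 in irisin HFD libraries; its log2 fold change on HFD, irisin against GFP, was 3.22 ± 0.61 and not called (adjusted p = 0.393). Transcripts of liver-type genes varied between iWAT libraries: the albumin gene Alb was at 2.74, 33.1 and 73.5 FPKM in GFP HFD 1, 2 and 3, 24.1 in GFP chow 3 and 19.7 in irisin HFD 2, and the apolipoprotein gene Apoa1 at 0.0412, 11.6 and 18.4 in GFP HFD 1, 2 and 3, 4.17 in GFP chow 3 and at most 0.278 in the other iWAT libraries.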
